A study of Homo sapiens with 4 samples.

How the data were processed

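Poly(A) RNA was sequenced from dendritic cells derived from THP-1, a human monocytic leukaemia line, on day 7 of differentiation. Per the labels, the cells received either the micropeptide P155 or a scrambled peptide (Scr) for 2 h and then the TLR7 and TLR8 agonist R848 at 1 µg/ml for a further 2 h. Of the 4 libraries, 2 were P155 (replicates 1 and 2) and 2 were Scr (replicates 2 and 3), with the group and replicate number taken from the titles. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

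The deposited table lists 31959 Ensembl genes with 1 log2 value per library, the mean of each group, and the authors' comparison. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.5.3a and DESeq2 with genome build hg38. The gene counter, the annotation release and the strand setting are not given in the sources used here. From the values, each deposited log2 value is the log2 of a gene's whole read number divided by a size factor of its library, plus 1. The reads recovered this way were whole within 0.01 reads for 100% of the values. The size factors lay within 0.246% of median-ratio factors recomputed from those reads. The authors' fold change column equals the difference of the group means of the log2 values, and their deposited FDR equals the Benjamini-Hochberg adjustment of their p-values over all rows. Their test is not stated in the file.

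Depth recovered from the values was 41171514 reads for P155 replicate 1, 37003456 for P155 replicate 2, 37799472 for Scr replicate 2 and 38677047 for Scr replicate 3. The value of 1 read was between 0.882 and 0.981 normalized counts. The 10 most abundant genes took 8.40% to 8.53% of the reads, and the mitochondrially encoded genes took 7.71% to 8.05%.

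The design fixed before the data were examined named a test on counts, with limma as its stand-in for any other unit. Because the table holds log2 values and not counts, limma 3.58.1 in R 4.3.3 was used (lmFit, then eBayes with a mean-variance trend) on the deposited log2(normalized count + 1) values. Genes at a normalized count of 1 or more in at least 2 libraries entered, which left 25712. P-values were adjusted by Benjamini-Hochberg and the threshold was an adjusted p of 0.05. Fold changes are P155 minus Scr on this log2 scale, which understates the change of low genes. Normalized counts are printed as mean ± SD with n = 2 per group. For a gene with 0 reads in both libraries of a group, a bound was computed from a floor of 3 reads in each library. The 95% intervals come from limma and cover the spread between these libraries, whereas the floor covers counting error only.

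A set of 26 gene lists was written before the data were examined: MHC class II and class I presentation, co-stimulation and maturation, cytokines, chemokines, type I interferon response, NF-kB targets, immediate early genes, TLR7 and TLR8 signalling, heat shock chaperones, unfolded protein and integrated stress response, lysosome and autophagy, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, cell cycle, p53 targets, published miR-155 targets, 5 marker lists for cell types (dendritic cell, macrophage, myeloid precursor, lymphocyte, fibroblast and epithelial), mitochondrially encoded genes, nuclear-retained or non-polyadenylated RNA, and ribosomal proteins. Each was tested with camera in limma with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the 26 lists. One symbol of the oxidative phosphorylation list stands on 2 rows of the table, and both rows were tested.

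The genes named follow a rule fixed at the same time. They are the 12 largest rises and 12 largest falls past the threshold with a mean of at least 5, a gene symbol and both P155 libraries on the same side of both Scr libraries, then up to 4 members of each list with the smallest p, then 18 genes fixed in advance (MIR155HG, HSPA8, HLA-DRA, HLA-DRB1, CD74, CIITA, CD80, CD86, CD40, TLR7, TLR8, TNF, IL1B, IL6, IL10, IL12B, IFNB1 and CXCL10). The first part gave 3 genes. RPS10-NUDT3 and AC145138.1, a read-through and a clone name, fell outside the rule and were named after their values were seen.

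The limma step was tested on simulated reads drawn for the real genes with 50 genes changed at each fold. The changed genes were drawn only from those with a mean normalized count of at least 50. Each gene kept its spread as moderated by limma. Among 24875 genes, limma called 14 of 50 genes changed by 1.5-fold and 29 of 50 changed by 2-fold. It called 47 of 50 changed by 4-fold and 48 of 50 changed by 8-fold, with 9 false calls. Many genes changed at once ease the adjusted threshold. These rates can therefore overstate the power in the real data, and they do not cover genes of lower level. With independent genes, camera called the MHC class II list at a simulated shift of 0.2 (log2) and called no list at a shift of 0. The step that finds genes held at 2 levels was also tested on simulated data and found all 300 of 300 stepped genes. The simulated steps were well over the required gap and the noise was small. This checks the code and does not cover genes near the cutoff.

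Alternatives covered size factors (median-ratio, upper-quartile, library totals), quantile normalization, the filter on low values, the pseudocount, the threshold, limma-voom on the recovered reads, and each library left out in turn. The fits without the trend, with robust eBayes and on subsets of genes were chosen after seeing the data. Gene positions, transcript numbers and overlaps came from GENCODE 29 (GRCh38), in which 31845 of the 31959 gene IDs (99.64%) were found. An overlapping gene is a listed gene that shares exon bases on the same strand, unless both strands are named. Shared sequence was measured as the percentage of all 50-base words of a gene's annotated transcripts that also occur in another gene. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.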

Results

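Transcript levels were measured by RNA sequencing in THP1-derived dendritic cells that had been given a peptide for 2 h and then R848 for 2 h. P155 is a micropeptide encoded in MIR155HG, the host transcript of miR-155, and Scr is a scrambled peptide that served as its control. R848 (resiquimod) is a small molecule that activates TLR7 and TLR8. Each group held 2 libraries, of 37003456 to 41171514 reads counted over genes, and no library without R848 or without peptide was analysed here. The comparison of P155 with Scr asks which transcripts of R848-stimulated dendritic cells differ when the micropeptide is given.

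The cells carried transcripts of antigen-presenting myeloid cells in both groups, at uneven levels. Among the lower ones in P155 and Scr were HLA-DPB1 (70.8 and 105 normalized counts), CD80 (46.6 and 48.1) and CLEC10A (229 and 286). CD74, the invariant chain of MHC class II, stood at 4692 ± 38.3 normalized counts in P155 and 4756 ± 274 in Scr (SD, n = 2 each), and the class II chain HLA-DRB1 at 3638 ± 96.8 and 3658 ± 114. The dendritic cell lectin CD209 was at 3966 ± 18.6 and 3833 ± 17.2, and the integrin ITGAX (CD11c) at 4778 ± 125 and 4634 ± 143; both were singled out after their values were seen. Transcripts of the neutrophil granule protease ELANE, a product of myeloid precursors, were also abundant, at 20348 ± 412 in P155 and 21963 ± 1058 in Scr. Of the R848 receptors, TLR7 was at 62.95 ± 5.76 and 66.6 ± 22.1 and TLR8 at 69.9 ± 19.7 and 85.1 ± 23.9. MIR155HG itself was at 554.76 ± 57.35 in P155 and 529.76 ± 49.96 in Scr, a log2 fold change of 0.07 (limma adjusted p = 0.980) that was -0.04 without P155 replicate 1, -0.03 without Scr replicate 3, 0.17 without P155 replicate 2 and 0.16 without Scr replicate 2.

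Across the transcriptome, 5 genes fell in P155 and 0 rose. PTTG1IP, which encodes a binding partner of securin, was at 1134.61 ± 53.04 normalized counts in P155 and 5559.43 ± 83.07 in Scr (SD, n = 2 each). The zinc finger transcription factor gene ZNF24 was at 1283 ± 84.6 and 4749 ± 219. FAM111A, which encodes a protease that acts in DNA replication and restricts some viruses, was at 926 ± 16.6 and 3115 ± 170. The 2 other genes were RPS10-NUDT3, a read-through of RPS10 and NUDT3, and AC145138.1, an unprocessed pseudogene, both named after their values were seen.

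**Figure D1:**
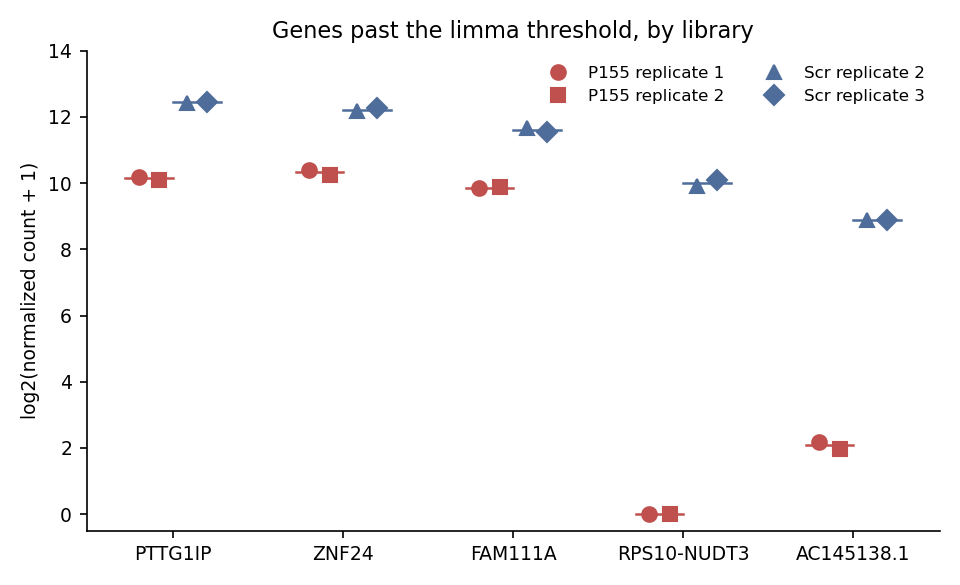
Log2(normalized count + 1) of the 5 genes past the limma threshold in each of the 4 libraries, with P155 in red, Scr in blue and a line at each group mean. Both P155 libraries lie below both Scr libraries for each gene, and RPS10-NUDT3 has 0 reads in P155.

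By limma, the log2 fold change of PTTG1IP (ENSG00000183255, chromosome 21, 44849585 to 44873903, GRCh38) was -2.29 with a standard error of 0.06 (95% interval -2.45 to -2.13, adjusted p = 0.016). For ZNF24 (ENSG00000172466, chromosome 18, 35332212 to 35345482) it was -1.89 ± 0.07 (SE, limma adjusted p = 0.0379). FAM111A (ENSG00000166801, chromosome 11, 59142748 to 59155039) had -1.75 ± 0.07 (SE, limma adjusted p = 0.0379). All 3 are protein-coding and share no exon base with another listed gene on their strand, whereas FAM111A overlaps 1 gene on the opposite strand, and the counting is not stated to use strand. RPS10-NUDT3 (ENSG00000270800, chromosome 6, 34284887 to 34426071) had 0 reads in both P155 libraries and 1023 ± 88.6 normalized counts in Scr. That is at least 366-fold lower, set against 3 reads in each library (limma adjusted p = 0.016). A switch of like size also crossed the treatment. TMEM189-UBE2V1, singled out after its values were seen, was at 1477 in P155 replicate 1 and 1110 in Scr replicate 3. It was at 0 in P155 replicate 2 and Scr replicate 2. AC145138.1 (ENSG00000251634, chromosome 5, 71102898 to 71128753) was at 3.24 ± 0.41 in P155 and 470 ± 0.24 in Scr, with a log2 fold change of -6.80 (limma adjusted p = 0.027). Both values are uncertain, because 95.8% of the annotated sequence words of RPS10-NUDT3 and 96.5% of those of AC145138.1 also lie in other genes. NUDT3 was at 8240 ± 173 in P155 and 8627 ± 710 in Scr, RPS10 at 39425 ± 572 and 41189 ± 2270, and NAIP, the gene that shares most with AC145138.1, at 1514 ± 43.4 and 1362 ± 13.8; these 3 were looked up after the values were seen.

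The counts rest on few libraries. Both other ways to set 2 libraries against 2 called more genes by limma than the treatment did. They called 9 (P155 replicate 1 and Scr replicate 2 against the others) and 8 (P155 replicate 1 and Scr replicate 3 against the others). At an unadjusted p of 0.05, 1364 of the 25712 genes passed in limma, where 1286 would by chance. Without P155 replicate 1 or without P155 replicate 2 limma called 0 genes, without Scr replicate 2 it called 27 (18 higher, 9 lower) and without Scr replicate 3 it called 12 (10 higher, 2 lower). Limma-voom on the recovered reads called 3 genes, PTTG1IP, ZNF24 and FAM111A, quantile normalization ended all 5 calls, and the smallest fall of FAM111A in any alternative was -1.69 (log2, without Scr replicate 2).

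No gene of the antigen presentation or co-stimulation lists passed the test. Among 21 tested members of the MHC class II list, 6 were higher and 15 lower in P155, with a median log2 fold change of -0.04 (camera adjusted p = 0.159, or 0.999 with an estimated correlation). HLA-DRA, the alpha chain of HLA-DR, was at 697 ± 36.8 normalized counts in P155 and 852 ± 54.6 in Scr, a log2 fold change of -0.29 (95% interval -0.53 to -0.05, limma adjusted p = 0.919). HLA-DPB1 was at 70.8 ± 4.02 and 105 ± 21.3 (log2 fold change -0.54, or -0.34 without Scr replicate 3). CIITA, the class II transactivator, was at 153 and 307 in the P155 libraries and 225 and 181 in Scr, and its log2 fold change of 0.10 was -0.40 without P155 replicate 2, -0.05 without Scr replicate 3, 0.60 without P155 replicate 1 and 0.26 without Scr replicate 2. The 21 MHC class I members divided into 10 higher and 11 lower (camera adjusted p = 0.999); among them, B2M was at 15277 in P155 replicate 1 and between 28522 and 30464 in the other 3 libraries. The co-stimulation and maturation list had 9 of 19 members higher (camera adjusted p = 0.850). CD40 was at 1017 ± 6.76 in P155 and 949 ± 31.9 in Scr (log2 fold change 0.10, or 0.07 without Scr replicate 3). CD80 was at 46.6 ± 3.51 and 48.1 ± 24.5, and its log2 fold change of 0.05 was -0.48 without Scr replicate 2, -0.03 without P155 replicate 2, 0.58 without Scr replicate 3 and 0.12 without P155 replicate 1. CD86 was at 252 and 392 in the P155 libraries and 400 and 382 in Scr, so its log2 fold change of -0.31 came from P155 replicate 1 and was 0.0028 without it and -0.63 without P155 replicate 2. HSPA8, the constitutive cytosolic chaperone HSC70 that P155 has been reported to bind, was at 55650 ± 813 in P155 and 49967 ± 1742 in Scr. Its log2 fold change was 0.16 (95% interval 0.05 to 0.26, limma adjusted p = 0.908).

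Cytokine, chemokine and interferon genes also held no member past the test. TNF was at 3319 ± 283 normalized counts in P155 and 3192 ± 4.96 in Scr, and IL1B at 762 ± 21.4 and 790 ± 97.0. For both the direction turned with 1 library left out, TNF to -0.03 without P155 replicate 2 and IL1B to 0.08 without Scr replicate 2 (log2), so none is given. IL12B, a subunit of IL-12, was at 108 ± 8.91 and 147 ± 43.3 (log2 fold change -0.41, or -0.11 without Scr replicate 2 and -0.71 without Scr replicate 3). IL6 (10.9 and 4.21), IL10 (13.1 and 11.9) and IFNB1 (5.10 and 4.25) had low mean normalized counts in P155 and Scr. IL15 was at 15.3 ± 0.82 in P155 and 2.80 ± 3.97 in Scr, and IL36G had 0 reads in P155 and a mean of 3.31 in Scr. Of 22 tested cytokines, 14 were higher and 8 lower in P155 (camera adjusted p = 0.646). Of 23 chemokines, 9 were higher (camera adjusted p = 0.851). CXCL10 was at 203 ± 15.5 in P155 and 243 ± 47.3 in Scr, and its log2 fold change of -0.24 was -0.04 without Scr replicate 2 and -0.44 without Scr replicate 3. The log2 fold change of CXCL3 was -1.18 from 17.5 normalized counts in Scr, and that of CCL24 0.75 from 29.3.

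The type I interferon response list had 14 of 38 members higher in P155 and a median of -0.03 (camera adjusted p = 0.851). LY6E was at 1057 ± 111 in P155 and 767 ± 51.6 in Scr (log2 fold change 0.46) and IFIT2 at 243 ± 10.6 and 310 ± 5.14 (-0.35), both at unadjusted p below 0.05 and neither past the limma threshold after adjustment. NF-kB targets (13 of 26 higher, camera adjusted p = 0.999), immediate early genes (16 of 32 higher, camera adjusted p = 0.999) and TLR7 and TLR8 signalling genes (9 of 23 higher, camera adjusted p = 0.851) were not called. TNFAIP3, the feedback inhibitor A20, had a log2 fold change of -0.09, or -0.05 without P155 replicate 2. EGR2 had 0.43 and FOSB 0.59, from 260 ± 16.0 and 60.2 ± 4.78 normalized counts in Scr. CXorf21, the TASL adaptor that links these receptors to IRF5, had -0.10, and IRF5 itself 0.09, or 0.04 without P155 replicate 1.

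No metabolic or stress gene of the lists passed over all genes. The glucose transporter gene SLC2A1, with the smallest p of any list member, was at 3996 ± 112 normalized counts in P155 and 7551 ± 415 in Scr (log2 fold change -0.92 ± 0.06 SE, limma adjusted p = 0.1). The lactate dehydrogenase gene LDHA was at 22389 ± 787 and 26873 ± 178 (log2 fold change -0.26, limma adjusted p = 0.578), and the oxygen-sensor hydroxylase EGLN3 had 0 reads in P155 and 8.98 ± 3.17 in Scr. These 3 of the 32 glycolysis and hypoxia genes passed when adjusted over the list alone; 16 members were higher and 16 lower (camera adjusted p = 0.646). INSIG1, a sterol-regulated factor that restrains SREBP cleavage, was at 1002 ± 88.0 and 1775 ± 106 (log2 fold change -0.83, limma adjusted p = 0.319). It was the 1 cholesterol synthesis gene to pass when adjusted over the list alone. Of 23 tested genes of that list, 18 were lower in P155, with a median of -0.05 (camera adjusted p = 0.159).

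SPI1, the myeloid transcription factor PU.1 and a published miR-155 target, was at 17209 ± 99.7 in P155 and 12014 ± 449 in Scr (log2 fold change 0.52 ± 0.04 SE, limma adjusted p = 0.182). It was the 1 gene of the 25 miR-155 targets to pass when adjusted over the list alone; 16 targets were higher and 9 lower (camera adjusted p = 0.206). Among 42 ribosomal protein genes, RPL14 (log2 fold change 0.57), RPL4 (0.30) and RPS2 (-0.32) passed when adjusted over the list alone, with 17 higher and 25 lower in all (camera adjusted p = 0.999). No member of any other list passed when adjusted over the list alone. Heat shock chaperones (16 of 31 higher, camera adjusted p = 0.999), lysosome and autophagy genes (18 of 34 higher, camera adjusted p = 0.999) and oxidative phosphorylation genes (14 of 37 rows higher, camera adjusted p = 0.829) were not called. The unfolded protein and integrated stress response list had 23 of 29 members higher with a median of 0.03 (camera adjusted p = 0.206), among them DDIT3 at 0.31. Cell cycle genes had 26 of 36 higher with a median of 0.02 (camera adjusted p = 0.206), with PCNA at 0.19, and p53 targets 6 of 21 higher (camera adjusted p = 0.301).

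**Figure D2:**
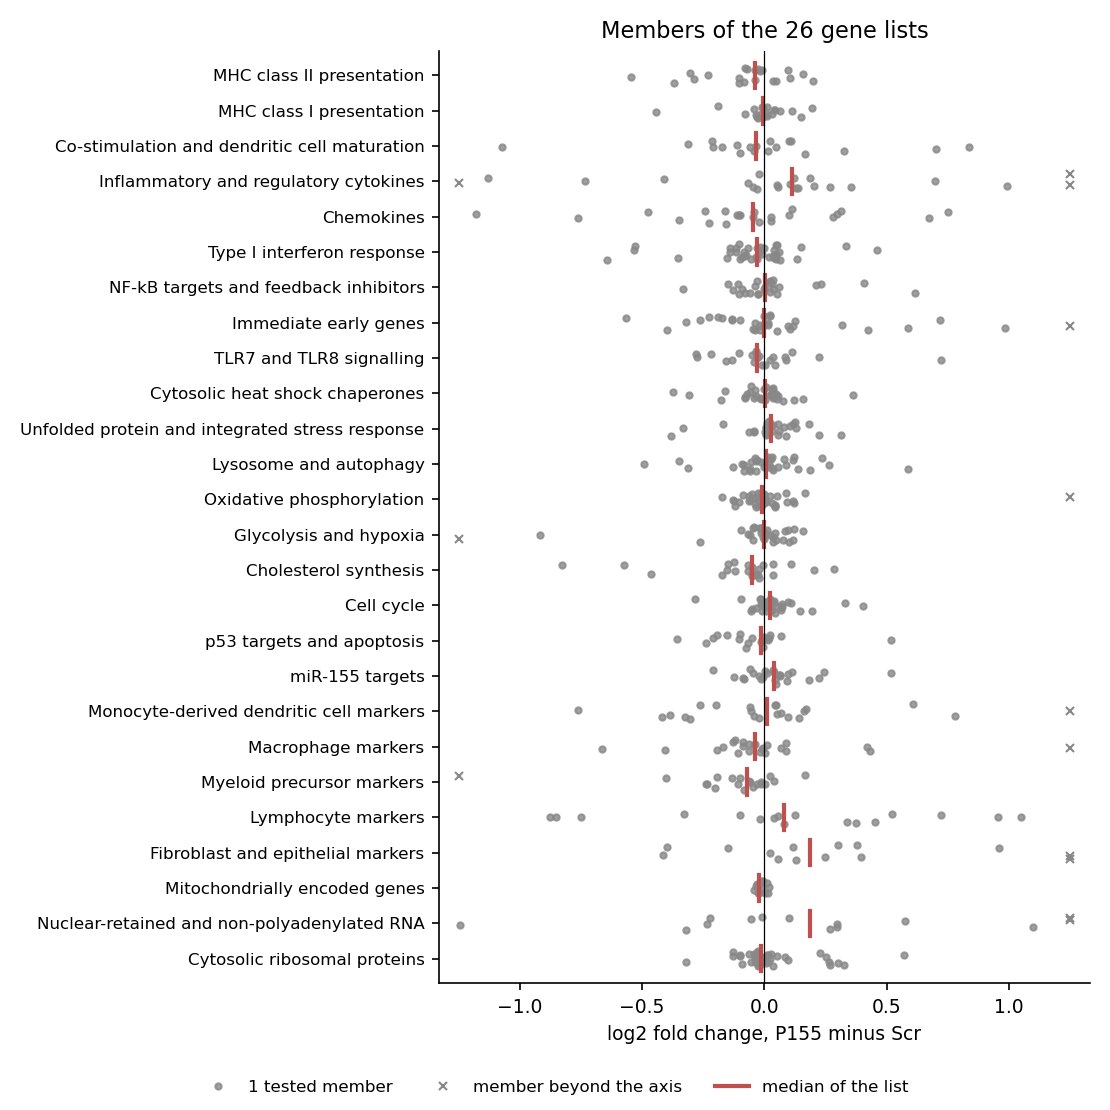
Log2 fold change (P155 minus Scr) of each tested member of the 26 gene lists, with a red line at each list's median and crosses for members beyond the axis. List medians lie between -0.07 and 0.19, and 0 of the 653 distinct genes tested passed the limma threshold.

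Markers of cell types and RNA quality gave no call either. The list nearest to the threshold was that of myeloid precursor markers, with 16 of 20 members lower in P155 and a median log2 fold change of -0.07 (camera adjusted p = 0.0542, or 0.999 with an estimated correlation). In it, MS4A3 was at 1100 ± 125 normalized counts in P155 and 1450 ± 14.2 in Scr (log2 fold change -0.40) and ELANE had -0.11, or -0.06 without Scr replicate 2. With library totals as size factors camera called 1 of the 26 lists (smallest adjusted p = 0.0401). Dendritic cell markers divided 11 to 11 (camera adjusted p = 0.999), with CLEC10A at -0.32 and FLT3 at -0.20, or -0.10 without P155 replicate 2. Macrophage markers had 8 of 24 higher (camera adjusted p = 0.829), lymphocyte markers 11 of 17 (camera adjusted p = 0.861) and fibroblast and epithelial markers 11 of 14 (camera adjusted p = 0.338), the last mostly at low levels such as CLDN3 with 9.81 normalized counts in P155. Mitochondrially encoded genes had a median of -0.02 (camera adjusted p = 0.646) and nuclear-retained or non-polyadenylated RNA of 0.19 (camera adjusted p = 0.684), where MALAT1 was at 20953 in P155 replicate 1 and between 9050 and 10029 in the other libraries. For MHC class I, NF-kB targets, immediate early genes, oxidative phosphorylation, glycolysis, p53 targets and ribosomal proteins the sign of the median depends on the size factors, which shift all genes alike (by 0.021 on the log2 scale for upper-quartile factors), and camera compares each list with the other genes. In all, camera called 0 of the 26 lists and the smallest adjusted p with an estimated correlation was 0.999. Directional fry called 0 lists, while fry's mixed test, which asks whether a set's genes change in either direction, called 5: cytokines, glycolysis, cholesterol synthesis, miR-155 targets and ribosomal proteins. The same mixed test called 12 lists when P155 replicate 1 and Scr replicate 2 were set against the other libraries and 2 lists in the remaining split.

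In the authors' deposited table, 156 genes had an FDR below 0.05, 66 higher and 90 lower in P155, and all 5 genes called by limma were among them. An overlapping gene was present for 41 of the 156 (26.3%), against 12.4% of all listed genes, which were not matched on level. Of the list genes, 10 were among the 156. In the authors' deposited table these included HSPA8 (log2 fold change 0.16, FDR 0.0139), SPI1 (0.52, FDR 4.56e-27), SLC2A1 (-0.92, FDR 2.85e-40), INSIG1 (-0.83, FDR 8.52e-11) and LDHA (-0.26, FDR 9.25e-07). HSPA8 and SLC2A1 have an overlapping gene, and SPI1, INSIG1 and LDHA have none. The others of the 10 were the ribosomal protein genes RPL14, RPL4, RPL7A, RPS2 and RPS3, and no MHC class II, cytokine, chemokine or interferon gene of the lists was among them. The authors' test was not run on the other pairings of the libraries. Tight separations were as frequent there. Among genes with a mean of at least 500, 76 had a P155 to Scr difference of at least 4 times the larger range within a group, above a small fixed minimum. The other pairings gave 104 and 75.

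Libraries of 1 group differed from each other about as much as libraries of different groups. Among 9020 genes with a mean normalized count of at least 500, the number over 2-fold apart was 145 between the P155 libraries, 149 between the Scr libraries, and 136 to 168 between a P155 and a Scr library. Some genes sat at 2 well-separated levels in pairs of libraries that cross the treatment. ZBED6 was at 10254 and 10038 normalized counts in P155 replicate 1 and Scr replicate 2 and at 878 and 834 in the other pair, and ZC3H11A, which contains ZBED6, was at 1251 and 1465 against 10417 and 10305. CAPZA1 was at 22686 and 22156 in P155 replicate 1 and Scr replicate 3 and at 11509 and 11357 in the other pair, a gap just under 2-fold. The immediate early gene MYC was at 198 in Scr replicate 2 and between 3528 and 5989 in the other 3 libraries, and MYD88, the adaptor of TLR7 and TLR8, was at 729 in Scr replicate 3 and between 2051 and 2210 in the others. These genes, with HNRNPH2, were singled out after their values were seen.

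**Figure D3:**
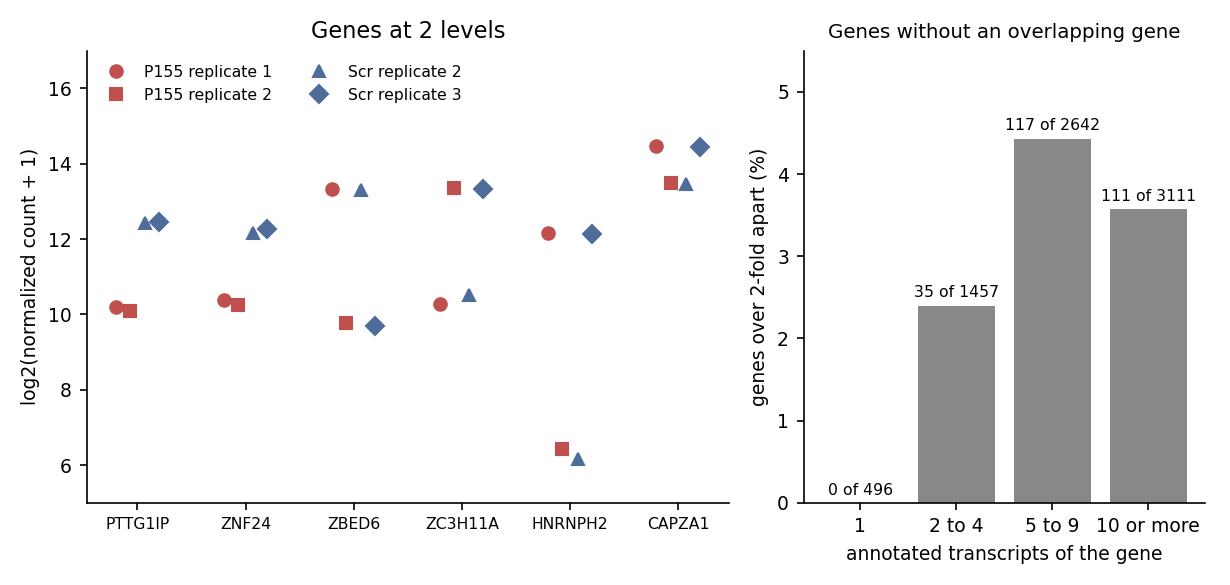
Left, log2(normalized count + 1) of 6 genes in each library, where PTTG1IP and ZNF24 part P155 from Scr, ZBED6 and ZC3H11A part P155 replicate 1 and Scr replicate 2 from the other libraries, and HNRNPH2 and CAPZA1 part P155 replicate 1 and Scr replicate 3. The gap of CAPZA1 is just under 2-fold, short of that required below for genes held at 2 levels. Right, percentage of genes with a mean of at least 500 and no overlapping gene that differ over 2-fold between any 2 libraries, by number of annotated transcripts, with 0 of 496 genes with 1 transcript, 35 of 1457 with 2 to 4, 117 of 2642 with 5 to 9 and 111 of 3111 with 10 or more.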

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

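Of the 4 counts reported (5 genes changed, 0 higher, 5 lower, 0 lists called), none moved under upper-quartile factors, and the direction of the 5 called genes held under each alternative that tested them. The numbers of genes changed and of genes lower were both 3 with no filter beyond 1 read in any library, with no filter on low values, with a pseudocount of 0.1, with limma-voom on the recovered reads and with genes of a mean of at least 500. Both were 2 with genes of 1 annotated transcript and no overlapping gene (AC145138.1, and AC020688.1, which is not among the 5), and both were 0 under quantile normalization, an adjusted p of 0.01 and limma without the trend. Robust eBayes called 18 genes, 5 higher and 13 lower. Lists called were 1 with median-ratio factors, with library totals and with quantile normalization. The gene subsets by mean, transcripts and overlap, and the limma fits without the trend and with robust eBayes, were chosen after seeing the data. Leaving out each library in turn (planned beforehand) gave 0 to 27 genes changed, 0 to 18 higher, 0 to 9 lower and 0 to 4 lists; the lone library left in a group is assumed to vary like the other group, and the cause of these moves was not tested. Genes called without Scr replicate 2 included MYD88, RNF6 and TTYH3, which were low in Scr replicate 3 alone. Those called without Scr replicate 3 included ADNP, RUNX3 and DDX3X, low in Scr replicate 2 alone (ADNP at 1291 normalized counts, against at least 5466). For these genes the difference came from the lone Scr library left. PTTG1IP, ASXL2 and UHMK1 were called in both fits. PTTG1IP and ASXL2 part both P155 from both Scr libraries, and UHMK1 is not among the genes held at 2 levels described below. Among single genes, 33 values of the 5 called genes lost significance without changing sign, SLC2A1 passed under robust eBayes (limma adjusted p = 0.0322), and 15 values moved, among them those of IL36G and EGLN3 under a pseudocount of 0.1. The planned count tests (the edgeR quasi-likelihood and likelihood-ratio tests and DESeq2) were not run, because the design named limma for other units. Whole reads could be recovered from the log2 values, and limma-voom was the only test run on them. No paired analysis was possible because the groups share only 1 replicate number. Depth limits low genes such as IL6 and IFNB1, at under 20 normalized counts.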

Other observations

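The tests of explanations in this part were chosen after the results were seen. Most of the 156 genes passed in the authors' deposited table and not by limma, and those named here were singled out after their values were seen. In the authors' deposited table, ASXL2, a Polycomb-associated chromatin factor, had a log2 fold change of 1.70 (FDR 3.42e-51), and SNU13, a component of small nucleolar ribonucleoproteins, of 1.28 (FDR 6.82e-49). The ubiquitin ligase subunit FBXO28 had -1.25 (FDR 4.58e-65) there and the calcium sensor STIM1 -0.79 (FDR 2.06e-19). By limma, the adjusted p was 0.0774 for FBXO28, 0.0951 for SNU13, 0.1 for ASXL2 and 0.138 for STIM1.

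A first pattern is a set of genes held at 2 levels across the 4 libraries: among 9020 genes with a mean of at least 500, 164 had a largest gap over 1 (log2) and a remaining range under 0.5; in 123 of them 1 library stood apart and in 41 the libraries parted 2 and 2. Treatment with P155 does not account for the set, because 13 genes part P155 from Scr against 18 and 10 for the other pairings. Reads shared by overlapping genes may account for some, since 10 of the 34 with an overlapping gene were level once summed with it, against at most 7 in 1000 draws of random genes of like expression (permutation p = 0.001, the smallest they can give), but not for all: 130 had no overlapping gene on the same strand, and 76 of these had none on either strand. Counting that depends on which annotated transcript is taken is a candidate explanation, since 0 of 496 genes with 1 transcript and no overlapping gene were over 2-fold apart, against 7 to 22 in the central 95% of 1000 draws of genes matched on level and transcript length (permutation p = 0.001, the smallest they can give) and 263 of 7210 genes with more transcripts. Against it, 4 genes of lower level among the 156 of the authors' deposited table have 1 transcript and no overlapping gene. AC145138.1, which is among them, cannot decide this, since 96.5% of its words lie in other genes. Shared sequence was not measured for the others. Also against it, the share of genes over 2-fold apart did not keep rising, at 4.43% with 5 to 9 transcripts and 3.57% with 10 or more.

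A second pattern is the fall of 5 genes in P155. Sequence shared with another gene is argued against for PTTG1IP, ZNF24 and FAM111A, of which at most 0.04% of the words lie in another gene. For AC145138.1 it may contribute, since genes that share its sequence, NAIP first, were higher by 244 normalized counts in P155 while its own difference was -466.7. For RPS10-NUDT3 it cannot be told apart, because the sharing genes differed by -2214 with a spread of 1220 and the loss was 1023. The 4 libraries allow only 3 splits, too few for a share under 0.05; all 3 called at least 5 genes, the highest other 9, and PTTG1IP, ZNF24, FAM111A and RPS10-NUDT3 also belong to the genes at 2 levels, so the peptide and the transcript-dependent counting both stay open for them.

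The split of P155 replicate 1 and Scr replicate 2 against the other libraries called 32 genes by limma-voom, where the treatment called 3, and 3 lists by camera (NF-kB targets, mitochondrially encoded genes and ribosomal proteins), but none with an estimated correlation (smallest adjusted p = 0.734). Spread of this size across the treatment is a limit on any call from 2 libraries per group, and its cause was not tested. All 13 genes at 2 levels that part P155 from Scr are among the 156 genes of the authors' deposited table. Their selection for a wide gap at a high level made this likely, so the overlap says nothing about its cause.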
